A study of Mus musculus with 12 samples.

How the data were processed

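Gene expression was measured by RNA sequencing of prefrontal cortex from male C57BL/6J mice, a standard inbred laboratory strain. Per the labels' protocols, mice received saline or 15 mg/kg cocaine from postnatal day 28 to day 42, had a pre-test on day 75, were given 1 mg/kg cocaine before training for conditioned place preference on days 76 and 77, and were tested on day 78. Conditioned place preference is a behavioural test of how strongly an animal seeks a place that was paired with a drug. Brain tissue was taken 30 to 60 min after the test and frozen, RNA was extracted with Trizol, and libraries were built from 1 µg of total RNA with an Illumina TruSeq kit, per the labels' protocols. There were 12 libraries, 6 per group, and each was assigned to saline or cocaine by its treatment label. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries.

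The labels also carry fields that do not match this tissue: a mesenchymal stem cell line, a time tag of day 0 or day 5 that alternates with the replicate number, and a human genome build, hg38. These fields were not used to form groups, and the time tag entered only as a covariate in an alternative. HISAT2 2.0.5 is named in the submitters' processing notes. The read counter, its strand setting and the annotation are not given in the sources used here. Gene IDs in the file are mouse IDs: 28825 of 28842 were found in GENCODE M21, and 28061 had the same start and end there, so coordinates are those of GRCm38.

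The authors deposited 1 table of the whole series. Per the file headers it holds a value per gene and library, the mean of each group, a gene length in bases (a column of another kind), a log2 fold change, a p-value and an adjusted p-value. The name of the table says FPKM, but its values are not divided by gene length. The values per library are a signal made by the authors from read counts divided by 1 size factor per library: in every library 100 percent of the values were whole multiples of the value of 1 read, within a tolerance of 0.01 read. The value of 1 read equalled 1 divided by the library's median-of-ratios size factor, computed from the recovered reads (ratio 1 in every library). Recovered reads ranged from 16.7 to 19.9 M per library, so a gene at 0 reads is limited to about 3 reads in that total, counting error only. The authors' log2 fold change and p-value columns were compared with DESeq2 1.42.0 run with default settings on the recovered reads: over 28827 genes the correlation of log10 p was 1, and among genes with a mean of at least 10 the log2 values differed by at most 7.88e-05. For 25 genes the name had been turned into a date by a spreadsheet, and the name was restored through the gene ID.

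The test, the filter, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined, when the values were assumed to be FPKM. That test was kept: limma 3.58.1 (linear model, empirical Bayes with a variance trend) in R 4.3.3 on log2(value + 1), two-sided, with no covariates, over all 12 libraries. FPKM for the filter was computed here from the value, the gene length and the column sum, and the 13016 genes with a mean FPKM of at least 1 were tested, 11637 of them protein coding. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Differences are given as log2 of cocaine over saline on the log2(value + 1) scale, which understates the change of low genes, and errors are standard errors of that model unless SD is named. Means and SDs are of normalised read counts, meaning the deposited values. For single genes and list scores an exact permutation test over all 924 splits of the libraries was run as well, two-sided; it cannot give a p below 0.00216.

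There were 31 gene lists. Each was tested with camera, which compares a list's genes with all other genes, with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data; fry was run beside it. A list score is the mean over members of each library's log2 deviation from the gene's mean. The rule for named genes took Dusp1, then in each direction the 10 genes with the largest change past the threshold, filled by the smallest unadjusted p, then the 4 members with the smallest p from the MAPK phosphatases, the rapid immediate-early genes and each list past the threshold, and 1 member from each other list. Unnamed predicted genes and pseudogenes took no place; 4 stood among those passed over in the lower direction and 0 in the higher one. The rule named 71 genes, and the values of some of them are not reported here.

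Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the variance model, library weights, the replicate number as a block, the time tag, a rank sum test, protein-coding genes alone and leaving out each library. Count tests on the recovered reads (edgeR 4.0.16 quasi-likelihood and DESeq2), marker and component covariates, a permutation of list scores, the estimated correlation of the immediate-early list without each library and with covariates, and the choroid plexus list with the same members without saline 5 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

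The tests were run on simulated data first. With counts drawn from these libraries' means for 13016 genes, limma recovered 58 percent of 100 genes changed by 1.5-fold and 95 percent of 100 genes changed by 2-fold in a simulated comparison of cocaine with saline, and called 11 of 12793 unchanged genes; edgeR recovered 58 and 97 percent. A simulated shift of 0.3 (log2) in the rapid immediate-early list was found by camera (adjusted p = 1.28e-07, and 0.00215 with an estimated correlation), and 0 other lists were called. The simulated genes were drawn independently, so this does not show how the list test behaves with correlated genes. In the real libraries other splits into 2 groups of 6 called a median of 7 lists with the preset correlation. Strand was not stated for the counting, so reads of neighbouring genes on the opposite strand may be counted where exons overlap. Among named genes for which the overlap is not given beside the value, such bases number 204 of 2734 in Gpr3, 322 of 4475 in Epc1, 669 and 244 of 5883 in Als2cl, 554 of 6865 in Tyk2, 547 of 2473 in Dusp5, 472 of 5895 in Crem, 874 of 3440 in Homer3, 188 of 5195 in Gpr17, 499 of 4516 in Aldh1l1 and 873 of 5774 in Csf1r; smaller ones and those of some others are not listed. No library was left out: the reads of each pair of libraries differed beyond sampling noise (chi-square over degrees of freedom from 4.82 to 91.4).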

Results

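The prefrontal cortex of adult mice that had received cocaine or saline in adolescence was profiled by RNA sequencing, 6 libraries per group. Both groups had received 1 mg/kg cocaine during place preference training as adults, so the comparison is of adolescent exposure (15 mg/kg against saline from postnatal day 28 to day 42) in animals with the same adult treatment. The series title names DUSP1 in the medial prefrontal cortex and a higher sensitivity to the drug in adulthood. Depth was alike between groups: 17.8 ± 1.18 M reads per saline library and 17.7 ± 0.697 M per cocaine library (SD, n = 6 each; exact permutation p = 0.898). Mitochondrial transcripts took 4.03 ± 0.753 percent of reads in saline and 3.91 ± 0.780 percent in cocaine libraries (SD, n = 6; exact permutation p = 0.775).

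Dusp1, a phosphatase that removes phosphate groups from MAP kinases and is itself induced by activity, was higher in the cocaine group. Its normalised read count was 528 ± 80.4 in saline and 834 ± 143 in cocaine libraries (SD, n = 6 each), a 1.57-fold difference (log2 0.66 ± 0.13 SE). The highest saline library stood at 620 and the lowest cocaine library at 639, so the groups did not overlap; the exact permutation p was 0.00216, the smallest the splits can give. Dusp1 (ENSMUSG00000024190) lies on the minus strand of chromosome 17 from 26505590 to 26508519 (GRCm38). In the limma test over all 13016 genes its adjusted p was 1.00, whereas the authors' deposited table gives an adjusted p of 0.0188 for it. Of its 3311 exon bases 11 are shared with Ergic1 on the opposite strand, and Ergic1 differed by 0.01 ± 0.07 (log2, SE).

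The genes with the smallest p-values beside Dusp1 were Nr4a1 and Arc, both known as genes that neuronal activity can induce, although activity was not measured here. Nr4a1, an orphan nuclear receptor (ENSMUSG00000023034, plus strand of chromosome 15, 101254269 to 101274795), had 1656 ± 186 normalised reads in saline and 2399 ± 315 in cocaine libraries, a 1.45-fold difference (log2 0.53 ± 0.10 SE). Arc, a cytoskeletal protein made at active synapses (ENSMUSG00000022602, minus strand of chromosome 15, 74669083 to 74672570), had 2010 ± 491 and 3978 ± 1148, a 1.96-fold difference (log2 0.97 ± 0.20 SE). In both genes every cocaine library lay above every saline library (SD, n = 6 each; exact permutation p = 0.00216). Nr4a1, Arc and Dusp1 were the 3 genes with an adjusted p under 0.05 in the authors' deposited table, all 3 higher, and each had an adjusted p of 0.0188 there.

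By limma 0 of 13016 genes passed the adjusted threshold. At an unadjusted p under 0.05 there were 149 genes, 88 higher and 61 lower, fewer than the 651 that uniform p-values would give. edgeR on the recovered reads passed 0 of 16057 genes, with 253 at an unadjusted p under 0.05, and DESeq2 passed 3, with 428. In 10 genes the groups did not overlap (8 higher, 2 lower), against 28.2 given by chance (0.216 percent).

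**Figure D1:**
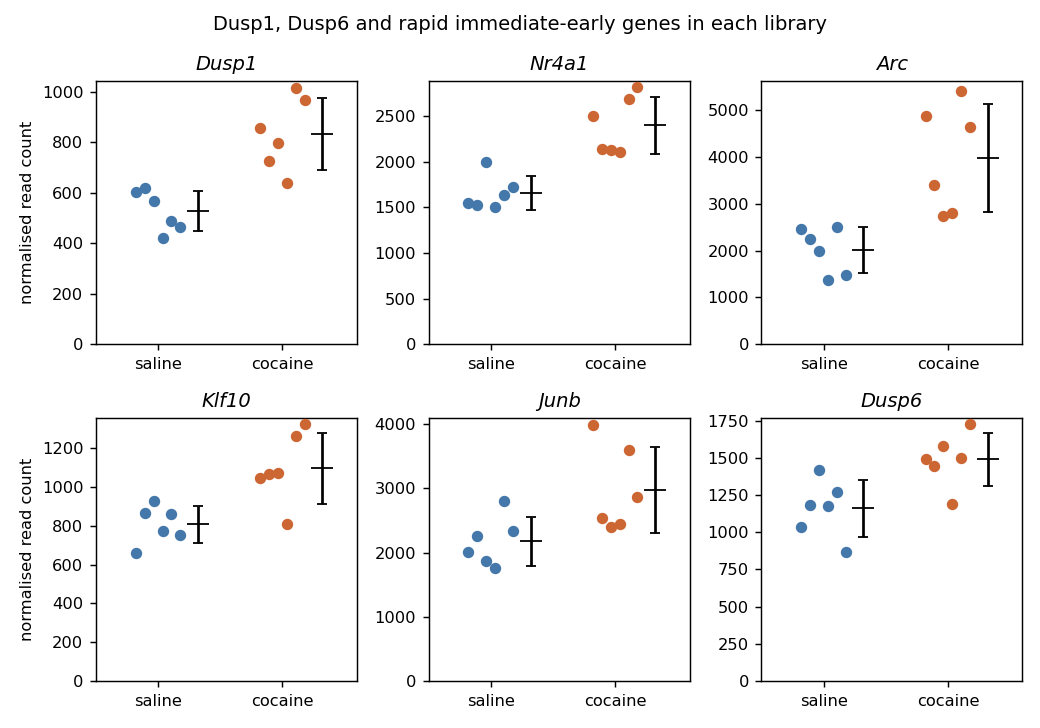
Normalised read counts (y axis, from 0) of Dusp1, Nr4a1, Arc, Klf10, Junb and Dusp6 in each saline (blue) and cocaine (orange) library, with the group mean and SD in black (n = 6). For Dusp1 the saline libraries reach 620 and the cocaine libraries start at 639; Nr4a1 and Arc also show no overlap, and the other genes do.

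None of the other genes that ranked highest passed the adjusted limma threshold. Fam84b had 140 ± 17.4 normalised reads in saline and 193 ± 24.1 in cocaine libraries (log2 0.45 ± 0.12 SE). Its groups did not overlap, but by a near tie: the highest saline library stood at 158.89 and the lowest cocaine library at 158.99. Of its 5926 exon bases 2474 are shared with a transcript on the opposite strand. Trib1, a pseudokinase, stood at 423 ± 64.3 and 603 ± 123 (1.41-fold), and Gpr3, a receptor that raises cyclic AMP, at 153 ± 22 and 205 ± 30.3 (1.34-fold). Insig1, which holds back sterol synthesis in the endoplasmic reticulum, stood at 1439 ± 134 and 1706 ± 119 (1.19-fold), Rbm43 differed by 0.25 ± 0.08 (log2, SE) and Rilpl2 by 0.34 ± 0.11.

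In the other direction Irak1, a kinase of interleukin-1 and Toll-like receptors, had 855 ± 60.6 normalised reads in saline and 731 ± 44.6 in cocaine libraries (log2 -0.22 ± 0.07 SE) with no overlap between groups (exact permutation p = 0.00216). Tyk2, a Janus kinase of interferon receptors, stood at 302 ± 33.1 and 243 ± 41.0, and Gbp3, an interferon-induced GTPase, at 104 ± 41.9 and 55.7 ± 13.3. Epc1, a subunit of a histone acetyltransferase complex, did not overlap between groups either (674 ± 23.9 and 589 ± 40.2). Cd248 differed by -0.43 ± 0.14 (log2, SE), Marveld1 by -0.27 ± 0.09, Als2cl by -0.41 ± 0.15 and Sbf2 by -0.23 ± 0.08. The list also held 2 small RNA genes, the mitochondrial transfer RNA mt-Tn (314 ± 74.2 and 185 ± 102) and the microRNA gene Mir145a (4.11 ± 1.68 and 0.841 ± 0.752). None of these passed the adjusted threshold in limma or DESeq2, nor in edgeR, which did not test Mir145a.

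As a group the rapid immediate-early genes, transcribed within minutes of neuronal activity, rose in the cocaine libraries. Of the 23 measured members 21 were higher and 2 lower, with a mean difference of 0.26 and a median of 0.19 (log2). Members ranged from -0.10 to 0.97. Past 0.05 adjusted over the list alone stood 5 members: Nr4a1, Arc, the transcription factors Klf10 (807 ± 95.7 and 1095 ± 183) and Egr2 (218 ± 29.1 and 271 ± 25.5), and the AP-1 subunit Junb (2174 ± 381 and 2971 ± 669); over all genes tested 0 did. Fos had 657 ± 119 and 862 ± 172 normalised reads and Btg2 233 ± 62.3 and 339 ± 88.8, neither past the list threshold (SD, n = 6 each). Egr1, the most abundant member, differed by 0.12 ± 0.10 (SE), Npas4 by 0.38 ± 0.31 and Homer1 by -0.10 ± 0.14. The camera adjusted p was 1.97e-17 with the preset correlation and 0.0173 with an estimated correlation, and this was the single list of the 31 that passed with both. With an estimated correlation the call was lost without any one of saline 3 or 4 or cocaine 1 or 2 (adjusted p from 0.0746 to 0.0883) and with the first component as a covariate (adjusted p = 0.135), and kept without each of the 8 other libraries. As covariates the red blood cell score (mean 0.205, adjusted p = 0.387) and the heat shock score (mean 0.219, adjusted p = 0.233) ended it too. The list score was -0.13 ± 0.12 in saline and 0.13 ± 0.14 in cocaine libraries (SD, n = 6 each; exact permutation p = 0.0108, adjusted over lists p = 0.335, where a single list can reach 0.0671 at best), and the fry adjusted p was 0.0834. Junb shares 173 of 2301 exon bases with Prdx2 on the opposite strand, which differed by 0.03 ± 0.11 (log2, SE).

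The MAPK phosphatases, the family of Dusp1, were split. Of 8 measured members 4 were higher and 4 lower, with a mean of 0.17 and a median of 0.12 (log2). Dusp1 and Dusp6, an ERK-specific phosphatase, passed 0.05 adjusted over the list alone; Dusp6 had 1161 ± 190 normalised reads in saline and 1490 ± 178 in cocaine libraries (1.29-fold). Dusp5 differed by 0.44 ± 0.16 and Dusp10 by -0.25 ± 0.18 (log2, SE). The camera adjusted p was 0.00813, and 0.197 with an estimated correlation. The list holds Dusp1 itself, which had its largest difference, and was not tested without that gene. With all genes of a mean FPKM of at least 0.1 kept, the mean was 0.11 and the adjusted p 0.0560, with no filter it was 0.0561, and at a minimum of 5 the mean was 0.29. By edgeR with no count filter the mean was 0.07. The MAPK pathway kinases and GTPases showed no shift (14 of 22 higher, mean 0.03, camera adjusted p = 0.530); Map2k3 had the smallest p among them, at 0.25 ± 0.15.

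The inflammatory and interferon genes fell as a list with the preset correlation. All 7 measured members were lower, with a mean of -0.48 and a median of -0.44 (log2); 0 passed over the list alone. Gbp3 was followed by Isg15, a ubiquitin-like interferon-induced protein (40.8 ± 22.3 and 21.6 ± 8.67 normalised reads), Bst2 (81.1 ± 32.4 and 52.2 ± 20.2) and Ifitm3 (199 ± 70.8 and 141 ± 24.4), 2 restriction factors against viruses. The camera adjusted p was 6.01e-09, and 0.197 with an estimated correlation, which was 0.723 between genes of this list. The list score was 0.24 ± 0.51 in saline and -0.24 ± 0.26 in cocaine libraries (SD, n = 6 each; exact permutation p = 0.0584). Saline 5 had the highest score of the list, 1.01, and was also the library with transcripts of choroid plexus.

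The remaining lists that passed with the preset correlation lost the call with an estimated one. Red blood cell genes were higher in 4 of 4 members (mean 0.53; camera adjusted p = 5.89e-05, and adjusted p = 0.252 with an estimated correlation), with a mean of 0.36 by edgeR with upper-quartile scaling and 0.34 with no count filter. Hbb-bs had 615 ± 236 normalised reads in saline and 835 ± 241 in cocaine libraries, Hba-a1 552 ± 362 and 719 ± 194, Hba-a2 93.1 ± 68.4 and 130 ± 36.7, and Hbb-bt 73.9 ± 36.9 and 94.9 ± 26.1. The alpha globin copies share near-identical sequence, as do the beta globin copies, so the split of reads within each pair is uncertain. Heat shock and chaperone genes were higher in 10 of 12 members (mean 0.10; camera adjusted p = 0.00612, and adjusted p = 0.353 with an estimated correlation), led by Hspa1b (154 ± 30.9 and 210 ± 67.4, with a near-identical copy in the genome) and Dnajb1 (1411 ± 57.6 and 1587 ± 186), and followed by Hspa5 (0.10 ± 0.08) and Hsph1 (0.10 ± 0.08). That call was lost without cocaine 2 (mean 0.06, adjusted p = 0.0888) or without cocaine 5 (adjusted p = 0.0656), and with library weights (adjusted p = 0.0690); at a minimum mean FPKM of 5 the mean was 0.06.

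Later activity-induced genes, which follow the immediate-early wave, were higher in 11 of 14 members (mean 0.10; camera adjusted p = 0.0232, and adjusted p = 0.631 with an estimated correlation), and 2 of them, Trib1 and Gpr3, passed adjusted over the list alone. Crem differed by 0.13 ± 0.09 and Inhba by -0.16 ± 0.13 (log2, SE). The call was lost without any one of saline 1, 5 or 6 or cocaine 1, 3, 5 or 6 (adjusted p from 0.0534 to 0.260), and the mean was 0.06 without saline 6. It was also lost at a minimum mean FPKM of 5 (mean 0.03, adjusted p = 0.983), with library weights (mean 0.06, adjusted p = 0.448) and with the oligodendrocyte score as a covariate (adjusted p = 0.0649). Chromatin modifiers were lower in 16 of 22 members (mean -0.05; adjusted p = 0.0484, and adjusted p = 0.610 with an estimated correlation); Crebbp, Dnmt1, Tet2 and Dnmt3a differed by -0.12 ± 0.09, -0.15 ± 0.11, -0.16 ± 0.15 and -0.12 ± 0.12. This call was lost without saline 1, 2 or 4 or cocaine 1, 3, 4 or 5 (adjusted p from 0.0506 to 0.665), and the mean was -0.01 without cocaine 3. It was also lost with library weights (mean -0.03), lower filters, rescaling to equal sums per gene length, no variance trend and edgeR (mean -0.08 with no count filter; adjusted p from 0.0568 to 0.308).

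**Figure D2:**
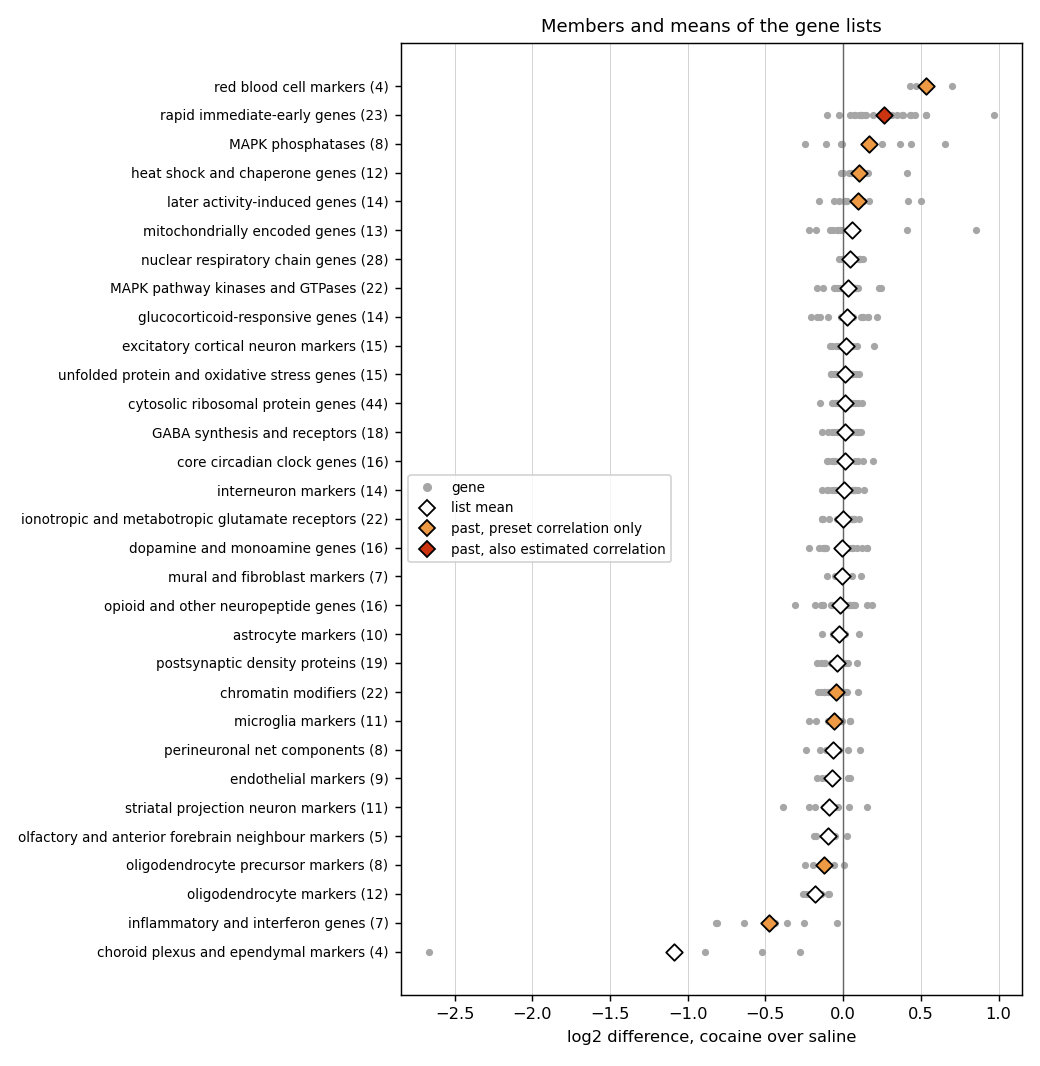
Log2 difference of cocaine over saline (x axis) for every measured member (grey points) and the mean (diamonds) of each of the 31 gene lists, with the number of measured members in brackets. Orange diamonds mark lists past the camera threshold with the preset correlation, and red the list that also passed with an estimated one, the rapid immediate-early genes (mean 0.26).

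Cell type markers were compared to see whether the tissue taken differed between groups. Microglia markers were lower in 9 of 11 members (mean -0.06; camera adjusted p = 0.0484, and adjusted p = 0.417 with an estimated correlation), with Cx3cr1 at 756 ± 83.1 and 651 ± 87.5 normalised reads, Csf1r at 1445 ± 109 and 1367 ± 57.3, Aif1 at 90.8 ± 17.7 and 80.6 ± 19.0, and Siglech at 222 ± 23.5 and 207 ± 22.8. This call was lost without saline 1, 5 or 6 or cocaine 1, 2, 4, 5 or 6 (adjusted p from 0.0513 to 0.374), and the mean was -0.03 without saline 1. It was also lost with other filters, rescaling, no variance trend, the time tag or the oligodendrocyte score as a covariate, and edgeR (adjusted p from 0.0502 to 0.218). Oligodendrocyte precursor markers were lower in 7 of 8 members (mean -0.12; adjusted p = 0.0484, and adjusted p = 0.667 with an estimated correlation), among them Gpr17 (-0.24 ± 0.18), Cspg4 (-0.11 ± 0.11), Neu4 (-0.14 ± 0.17) and Olig2 (-0.20 ± 0.29). That call was lost without saline 1, 2, 5 or 6 or cocaine 1, 3, 5 or 6 (adjusted p from 0.0575 to 0.579), and the mean was -0.04 without saline 1 or cocaine 1, -0.06 without saline 5, -0.20 without saline 3 and -0.21 without saline 4 or cocaine 4. With library weights the mean was -0.03 (adjusted p = 0.692) and with the oligodendrocyte score as a covariate -0.07 (adjusted p = 0.122), and the call was also lost with other filters, rescaling, no variance trend, the first component as a covariate and edgeR with no count filter (adjusted p from 0.0544 to 0.146).

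Myelinating oligodendrocyte markers were lower in 12 of 12 members (mean -0.18) with a spread between libraries that exceeded the difference: the score was 0.09 ± 1.12 in saline and -0.09 ± 0.70 in cocaine libraries (SD, n = 6 each; exact permutation p = 0.734), and the camera adjusted p was 0.104. The mean turned to 0.05 without saline 1, 0.02 without saline 5 and 0.01 without cocaine 1, and the list passed at -0.40 without saline 3, -0.50 without saline 4, -0.27 without cocaine 3 and -0.39 without cocaine 4. Aspa, the member with the smallest p, had 327 ± 181 and 264 ± 135 normalised reads. Choroid plexus and ependymal markers were lower in 4 of 4 members (mean -1.09; camera adjusted p = 0.0769), and Ttr, the transthyretin made in choroid plexus, was at 11208 in saline 5 and at 13.2 or below in every other library. The list mean rests on that library: with the same 4 members and without saline 5 it was -0.25 (exact permutation p = 0.816). It was -0.68 without cocaine 1 and -0.71 without cocaine 5, and the list passed at -1.58 without saline 3, -1.64 without saline 4, -1.46 without cocaine 3 and -1.48 without cocaine 4.

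Of the remaining cell type lists, the red blood cell genes above passed and the others did not. Camera adjusted p was 0.0953 for endothelial markers (mean -0.07; Tek -0.17 ± 0.17), 0.693 for astrocyte markers (mean -0.02; Aldh1l1 0.10 ± 0.12), 0.874 for mural and fibroblast markers (mean -0.01; Col1a2 0.11 ± 0.14) and 0.874 for excitatory cortical neuron markers (mean 0.02; Slc17a6 0.20 ± 0.13). It was 0.935 for interneuron markers, whose mean was 0.00 while the test pointed lower (Adarb2 -0.11 ± 0.11), 0.208 for striatal projection neuron markers (mean -0.09; Drd1 0.16 ± 0.17) and 0.360 for olfactory and anterior forebrain neighbours (mean -0.10; Dlx5 -0.19 ± 0.27). Endothelial markers passed without saline 2 or 6 or cocaine 2, and striatal markers without saline 3 or 6 or cocaine 4, with means of up to -0.13 and -0.20. With other libraries left out the means shrank to as little as -0.04 for endothelial and -0.02 for striatal markers. The olfactory mean turned to 0.06 without saline 5.

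**Figure D3:**
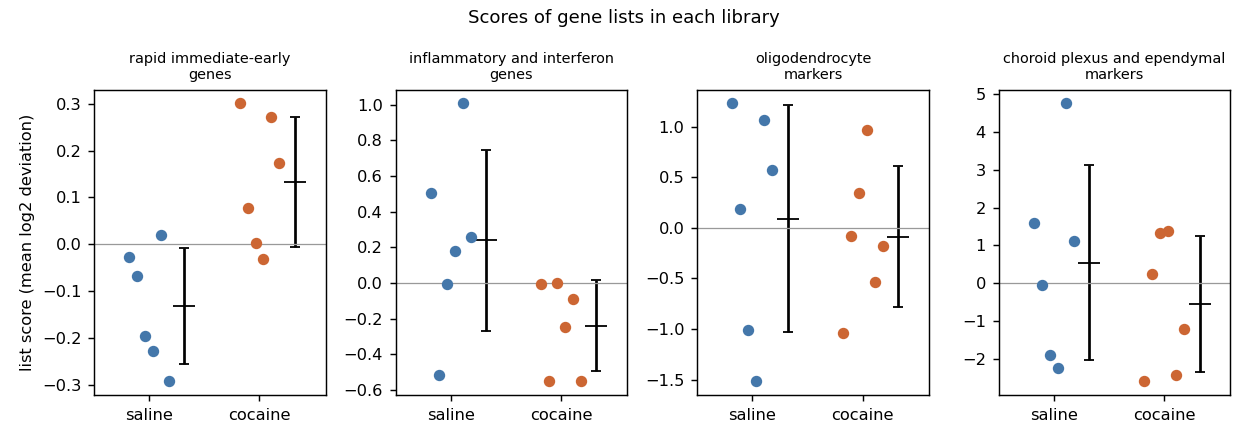
List scores (y axis, mean log2 deviation of the members from their means) of the rapid immediate-early genes, the inflammatory and interferon genes and the oligodendrocyte and choroid plexus or ependymal markers in each saline (blue) and cocaine (orange) library, with group mean and SD in black (n = 6). The immediate-early score averages -0.13 in saline and 0.13 in cocaine libraries, and saline 5 has the highest inflammatory score, 1.01.

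No neurotransmitter list passed either. Glutamate receptors had a mean of 0.00 and a median of 0.01 over 22 members (camera adjusted p = 0.943; Grik1 -0.14 ± 0.13), with the test pointing lower. Genes of GABA synthesis and its receptors had a mean of 0.01 over 18 members (adjusted p = 0.943). Dopamine and monoamine genes had a mean of -0.01 and a median of 0.03 over 16 members (adjusted p = 0.943; Adrb1 0.12 ± 0.09), and opioid and other neuropeptide genes a mean of -0.02 and a median of 0.03 over 16 (adjusted p = 0.924), with the test pointing higher in both. Crhbp, which binds corticotropin-releasing hormone, had 459 ± 44.6 normalised reads in saline and 508 ± 16.1 in cocaine libraries (SD, n = 6 each; exact permutation p = 0.0238, not past the threshold over all genes). Postsynaptic density proteins were lower in 14 of 19 members (mean -0.04, adjusted p = 0.218, past the threshold without saline 5 or 6 or cocaine 2 or 6, and turned to 0.01 without saline 4 or cocaine 3; Homer3 -0.17 ± 0.20) and perineuronal net components in 6 of 8 (mean -0.06, adjusted p = 0.360; Hapln4 0.11 ± 0.13).

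The other stress and housekeeping lists did not pass. Glucocorticoid-responsive genes had a mean of 0.03 (camera adjusted p = 0.750; Fkbp5, a stress-induced chaperone of the glucocorticoid receptor, 519 ± 82.0 and 445 ± 40), core circadian clock genes 0.01 (adjusted p = 0.989; Bhlhe40 2702 ± 364 and 3072 ± 184), and unfolded protein and oxidative stress genes 0.01 (adjusted p = 0.822; Xbp1 0.08 ± 0.07). Nuclear respiratory chain genes were higher in 25 of 28 members by a mean of 0.05 (adjusted p = 0.0710; Sdhd 0.13 ± 0.08). They passed without saline 5 or 6 or cocaine 2, 4 or 6, and the mean turned below 0 without saline 4 or cocaine 1 (-0.01 without cocaine 1). Mitochondrially encoded genes had a mean of 0.06 and a median of -0.02 with the test pointing lower (adjusted p = 0.943); they passed without cocaine 3 (mean -0.01), and the mean was -0.01 without saline 4. mt-Atp8, which overlaps mt-Atp6, differed by 0.86 ± 0.45 at 9.01 ± 5.00 and 18.5 ± 12.5 normalised reads. Cytosolic ribosomal protein genes had a mean of 0.01 over 44 members (adjusted p = 0.935), from -0.07 without saline 4 to 0.10 without saline 5, and passed without saline 3, 4, 5 or 6 or cocaine 2.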

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

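The outlier check compared, within each group of 6, the gap between the most extreme library and its neighbour with the range of the group (Dixon's ratio above its critical value). It was applied to 210 groups of values, where chance gives about 10.5, and 11 stood out, so the number itself is what chance gives. The tests of a covariate for white matter, blood and heat shock, of the first component, of the list without saline 5, and of the strongest list over other splits, were chosen only after the results they bear on were seen.

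Ttr stood at 11208 normalised reads in saline 5 and between 1.10 and 12.6 in the other saline libraries. Saline 5 also had the lowest Adarb2 of its group, 195 against 260 to 305, and the highest score of unfolded protein and oxidative stress genes, 0.097 against -0.048 to 0.0064. The dopamine and monoamine score of saline 6 was -0.26 against 0.0069 to 0.098, Irak1 in saline 1 was 973 against 800 to 858, and Mir145a in saline 4 was 1.06 against 3.60 to 5.54. Among cocaine libraries mt-Tn was 386 in cocaine 1 against 104 to 169, Dnmt1 was 821 in cocaine 3 against 1082 to 1272, and Adarb2 was 294 in cocaine 2 against 217 to 242. The score of later activity-induced genes was -0.14 in cocaine 4 against 0.066 to 0.15, and mitochondrial reads made up 5.43 percent in cocaine 3.

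The higher level of rapid immediate-early genes was weighed against chance, white matter, blood, tissue stress and a library gradient. Of 100 splits drawn from 462, 1 gave this list a camera statistic as large, the real one (8.89, against 6.67 for the highest other split). Any of the 31 lists reached one as large in 2 splits, the real one included (9.62 in the highest other). Such a split was rare on this statistic, which uses the preset correlation of 0.01, but chance is not excluded. The fry adjusted p was 0.0834, and exact permutation of the list score gave p = 0.0108. Adjusted over lists the permutation p was 0.335, but a single list can reach 0.0671 at best, so this failure says little. With the oligodendrocyte score as a covariate the mean difference was 0.263 ± 0.081 (SE) against 0.264 ± 0.076 without it. Camera then gave an adjusted p of 0.0360 with an estimated correlation. The oligodendrocyte score differed little between groups against its spread (0.09 ± 1.12 in saline, -0.09 ± 0.70 in cocaine libraries, SD), so this covariate could hardly move the difference. The fit shows only that the measured score carries little of the 0.264. With the red blood cell score, also higher in cocaine libraries, the difference was 0.205 ± 0.081 (adjusted p = 0.387). That lies within 1 SE of 50 percent of 0.264, which leaves blood in the tissue open. With the heat shock score it was 0.219 ± 0.079 (adjusted p = 0.233), above 50 percent of 0.264 by barely more than 1 SE. That margin is too narrow to decide, so tissue stress stays open as well. With either of these 2 scores the call ended, with a smaller difference and a slightly larger SE. The first principal component differed between groups by 0.029 against an SD of 30.7 in saline and 19.9 in cocaine libraries. By its slope within groups it therefore carries -6.68e-05 ± 0.034 (log2, SE from the group difference) of the 0.264, which argues against this gradient as the cause. As a covariate it cannot move the difference (0.264 ± 0.072). The camera call ended there (adjusted p = 0.135), and the estimated correlation between members went from 0.132 to 0.219. Whether that correlation alone ended the call was not tested. Adolescent exposure, blood in the tissue, tissue stress, chance and any white matter difference beyond the oligodendrocyte score stay open. So does the time of 30 to 60 min between test and collection, which is not given per library. A biological reading is a hypothesis.

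The lower inflammatory and interferon genes could come from the makeup of single tissue pieces. Of 100 splits 5, the real one included, gave a statistic as large as the real one (6.26, against 7.82 for the highest other), so chance is not excluded. Without saline 5 the mean difference was -0.33 ± 0.20 (SE; exact permutation p = 0.130) against -0.48 with it; camera with the preset correlation still passed (adjusted p = 0.00053), but the exact permutation did not and 50 percent of -0.48 lies within 1 SE, so the part of that library stays open. With microglia and endothelial scores as covariates it was -0.25 ± 0.19 (SE) against -0.48 ± 0.23, an interval too wide to separate cell content from a change in expression.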

How the results depend on the processing

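Chosen after the data were seen were the count tests, the marker and component covariates and the permutation of list scores. The 1.57-fold Dusp1 difference kept its direction and an unadjusted p under 0.05 in all 33 alternatives, and without each library in turn it ranged from 0.59 to 0.73 (log2). The count model fixed for raw counts was not run as such, since the file holds none. By limma and edgeR 0 genes passed in every alternative, and DESeq2 passed 3. The rank sum test passed 0, which says little: its p cannot go below 0.00216, where 564 genes would be needed for any to pass and 10 stood. Genes at an unadjusted p under 0.05 (149) numbered 406 with a minimum mean FPKM of 0.1, 715 with no filter and 49 with a minimum of 5, where 20042, 28842 and 7679 genes were tested. They numbered 322 with library weights, 253 by edgeR, 246 with upper-quartile scaling, 860 with no count filter, 428 by DESeq2 and 422 with the first principal component as a covariate; the cause was not tested. Without each library they ranged from 122 to 205.

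Lists past the threshold (9) numbered 5 with no filter, 5 with a minimum of 5, 5 with library weights, 1 with an estimated correlation, 0 with fry and 0 by permutation of list scores, where a single list can reach an adjusted p of 0.0671 at best, so that this 0 says little, and from 4 to 13 without each library (4 without cocaine 5, 5 without cocaine 1 or without saline 1); the cause was not tested. With the preset correlation in each alternative that does not name another, the rapid immediate-early genes passed in 32 of 34 settings (adjusted p from 3.49e-21 to 0.335), the inflammatory genes in 30 of 33, red blood cell genes in 31, MAPK phosphatases in 29, heat shock genes in 28, later activity-induced genes in 21, chromatin modifiers in 16, oligodendrocyte precursors in 14 and microglia in 13 of 34. At a minimum of 5 only 28 lists had 3 members, and the inflammatory genes were not among them. Robust variances do not enter the list test, and the rank sum test was not run for lists. With a replicate block 0 genes and 10 lists passed, 150 genes had an unadjusted p under 0.05 and Dusp1 differed by 0.66. Of the 22 lists not past the threshold, 18 had a mean that changed sign and 8 passed without some library, and 0 of the 9 others changed sign. The numbers do not pair the libraries: same-numbered deviations correlated from -0.40 to 0.43, and 2 of 12 libraries correlated best with their own number.

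Of the other named genes 2 changed sign: Aspa (-0.26) was 0.012 with library weights, and Dlx5 (-0.19) was 0.048 without saline 5 and -0.38 without saline 4; the cause was not tested. Nr4a1 and Arc passed only with DESeq2. In the simulation limma recovered 58 percent of the genes changed by 1.5-fold, and smaller changes were not simulated. Its genes were drawn independently, without the gradient between libraries seen here, so that share need not hold for this comparison. In the real libraries Dusp1 (1.57-fold) and Arc (1.96-fold) did not pass the adjusted limma threshold.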

Other observations

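The tests of the gene groups named here, of Gapdh and of the first component were chosen only after the ranking of genes or the values had been seen. In that ranking 3 groups of genes not among the lists drew attention, and each was tested without the members that had been seen. Sterol synthesis genes, without Insig1 and Cyp51, were higher in 16 of 18 members by a mean of 0.11 (log2; camera p = 0.0167 with an estimated correlation, adjusted over 3 groups p = 0.0502; exact permutation of the score p = 0.108), with Hmgcs1 at 5513 ± 583 normalised reads in saline and 6152 ± 448 in cocaine libraries (SD, n = 6 each) and Sqle at 1509 ± 189 and 1702 ± 158. The adjusted p lies above 0.05, so a coordinated rise of this pathway is a hypothesis. Antigen presentation genes, without Tap1, Nlrc5 and B2m, were lower in 7 of 11 members by a mean of -0.17 (p = 0.0371, adjusted p = 0.0557; exact permutation p = 0.149), with H2-K1 at 564 ± 164 and 405 ± 45.8 and H2-D1 at 903 ± 203 and 743 ± 35.4. These genes belong to a family with near-identical copies, and the split of reads among them is uncertain. Feedback genes of the ERK pathway, without the Dusp genes, were not shifted (10 of 16 higher, mean 0.05, camera p = 0.242, exact permutation p = 0.325); 2 of them, Egr4 and Errfi1, also stand in fixed lists.

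Gapdh, a glycolytic enzyme often used as a reference gene, had 115 to 211 normalised reads in saline 1 to 5 and 124 in cocaine 6, but 2761 in saline 6 and 4386, 1210, 4203, 3531 and 5763 in cocaine 1 to 5 (log2 difference 2.95 ± 0.94 SE, not past the adjusted limma threshold). A change of glycolysis is argued against by the other 16 genes of the pathway, whose median difference was 0.044 with a spread of 0.032 (median absolute deviation). Reads shared with pseudogenes remain possible. Pooled over all annotated Gapdh transcripts there were 4958 distinct 100-base stretches, so the share within any single transcript was not computed and can be higher. Word for word, 1034 of them stand in transcripts of other genes, and 1 processed pseudogene, Gm7336, holds 1031. The shared stretches are 20.9 percent of the pooled ones and lie in 86 other genes. The summed reads of the 79 of these in the table ran from 509 to 904 per library, and with them the SD over the mean was 0.853 against 1.11 for Gapdh alone, but reads that map to several places might not have been counted at all, so this stays open.

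The 12 libraries have a structure that does not follow the groups. The first principal component held 43.4 percent of the variance, and its mean was -0.01 ± 30.7 in saline and 0.01 ± 19.9 in cocaine libraries (SD, n = 6; exact permutation p = 0.996). Across genes, which are not independent, its loadings went with gene length (Spearman 0.52, Pearson 0.39) more than with transcript GC (Spearman -0.16), so that longer genes were higher at one end. Across libraries it also went with some list scores, whose genes enter the component themselves. These correlations over libraries are another measure than those over genes and cannot be ranked against them. The correlation was -0.99 for cytosolic ribosomal protein genes and -0.95 for nuclear respiratory chain genes. It was 0.96 for MAPK pathway kinases and GTPases and 0.95 for glutamate receptors. Of 100 splits of the libraries, the real one included, 70 gave at least the 149 genes with an unadjusted p under 0.05 (6228 in the highest other), and 32 gave at least the 9 lists (15 in the highest other). Chance is not excluded for these counts. For genes past the adjusted threshold the comparison decides nothing, since all 100 splits must reach the real count of 0; 8 other splits passed genes, with 4786 in the highest. Splits that call that many genes point to a structure of the samples. In these 8 splits the first component differed between the groups by a median of 30.3 (2.19 to 39.4), and in the 91 other splits by 8.39 (0.083 to 31.6); this difference was not tested.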
